A study of Mus musculus with 12 samples.

How the data were processed

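The deposited files held raw counts of unique molecules per gene and barcode, which per the submitters' processing notes came from Cell Ranger 9.0.0 on mm10, and counts of hashtag molecules from matching libraries. The 12 samples were 6 gene libraries and 6 hashtag libraries, with 10 hashtags per library. The metadata table had 50 entries that link hashtags to mouse, organ and time. The chemistry version and the sequencing depth targets were not given in the sources used here.

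Barcodes were kept with 200 or more genes and under 10% mitochondrial molecules. Hashtags were called with HTODemux (Seurat 5.3.0) at a quantile of 0.99, and barcodes with more than 1 hashtag or none were left out. Hashtag doublets numbered 367, 544 and 1233 in the ZT1 libraries and 194, 549 and 2326 in those of ZT13, and barcodes with no call 541, 17 and 29, and 192, 43 and 19. Scrublet found 0 of 7853 cells in the pooled ZT13 library and 19.3% in the ZT1 library of artery and blood, so its calls served as an alternative only. Cells were clustered with scanpy 1.11.5 on 2000 variable genes without clock genes, 30 components, 15 neighbours and Leiden resolution 1.0. Clusters were named from fixed marker lists, and 10 of 43 stayed unnamed.

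Counts were summed per mouse and cell type. Types with 10 or more cells in 3 or more mice per time were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr), and genes with an adjusted p under 0.05 by Benjamini-Hochberg within the type were called. Adjusted p values of single genes are from edgeR unless DESeq2 is named. The differences between types in the change with time used edgeR with mouse as a block. Lists were tested with camera (limma 3.58.1) at a correlation of 0.01, with an estimated correlation and with fry. Shares of cell types were tested by exact permutation of mice over both times for mice with 20 or more cells. Pooled organs have 1 sample per time, and their values are scaled counts (CPM) with exact 95% Poisson intervals. A gene passed the size rule there when the intervals did not overlap and 20 or more molecules were seen. Ratios with 0 counts in the lower group are given as bounds against a floor of 3 counts.

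The design and the lists were fixed before the data were examined. Some of the other settings were chosen after seeing the data and are named as such. Genes were named by a fixed rule: the 10 rising and 10 falling genes with the smallest adjusted p, the called members of the lists, and Arntl, Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp and Ciart where tested. Genes with Gm or Rik names and those of ribosomal proteins and the mitochondrial genome were left out. Where fewer than 5 genes were called, the 5 with the smallest p in each direction are given as values. In organs the 5 largest folds each way and genes shared by 4 or more organs were eligible. Some genes that the rule gave are not reported here.

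The 21 fixed lists were core clock, clock positive arm and its phase, clock E-box and D-box outputs, glucocorticoid response, immediate early and dissociation response, heat shock and temperature, neutrophil ageing and homing, neutrophil primary granules, neutrophil secondary and tertiary granules, leukocyte adhesion on endothelium, chemokines, inflammatory cytokines and NF-kB targets, interferon response, foam cell and lipid handling, cholesterol synthesis and uptake, antigen presentation by MHC class II, extracellular matrix, smooth muscle contractile, proliferation, hypoxia and glycolysis, and neutrophil extracellular trap and oxidative burst.

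Simulated changes of 4-fold were recovered for 100% of changed genes in endothelial cells, fibroblasts, macrophages and blood neutrophils, 98% between artery and blood, and 91.5% in cluster 12. Changes of 2-fold were recovered for 67%, 63.8%, 71%, 79.6%, 58.9% and 34% of genes, with endothelial cells first and cluster 12 last. False calls numbered 3 in fibroblasts to 10 in blood neutrophils. The simulated counts followed each gene's mean and the dispersion trend, with 200 changed genes. They held no outlying mice and no shift between libraries, so recovery in the real data can be lower. Free RNA was measured in barcodes with 10 to 100 molecules. The gene span offset used a lowess trend (span 0.3) of counts on genomic span per mouse. Other tools were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.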

Results

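Single cells of ApoE-deficient mice, a strain prone to atherosclerosis, were profiled after 16 weeks on the diet the labels call HFD. Cells were taken at zeitgeber time 1 (ZT1) and 13 (ZT13), in hours after lights on, from 5 mice per time. Each time had 3 droplet libraries of gene counts, each with a matching library of hashtag counts. The first held cells of the brachiocephalic artery, a branch of the aortic arch that forms plaques in these mice, sorted to enrich several populations. The second held artery cells that were not enriched, together with blood of the same mice. The third held bone marrow, spleen, blood and perfusates of lung and liver pooled over mice, and part of these cells had been enriched for the receptor Kit. Unique molecular identifiers (UMIs) per library were 43821318, 33113595 and 42703255 at ZT1 and 20911766, 38166654 and 68377440 at ZT13, in that order. Of 20749 deposited barcodes, 12105 were used, and their median depth ranged from 4637 UMIs in the pooled ZT13 library to 17645 in the enriched ZT13 artery library. The comparisons asked how transcripts and cell types of artery, blood and blood-forming organs differ between the 2 times. Each time sits in its own libraries, so time and library cannot be told apart in any comparison between times, and the numbers 1 to 5 of the mice name different animals at ZT1 and ZT13.

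Clustering gave 43 clusters, of which 33 were named to 20 cell types by their markers, and each name here means cells like that type. Neutrophils were the largest type with 5175 cells, followed by 1159 T cells, 796 macrophages, 632 neutrophil precursors, 489 fibroblasts and 390 endothelial cells. Cluster 12, with 220 cells, stayed unnamed. Its leading genes included the coagulation factor gene F10, Thbs1, the lectin gene Cd209a and the antigen presentation gene H2-Ab1.

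Fibroblasts of the artery differed between the 2 times in 12 of 17 tested core clock genes. Transcripts of the repressor genes Per3 and Per2 and of the D-box activator genes Tef and Dbp were all higher at ZT13, while those of the activator genes Npas2 and Arntl (Bmal1) were lower. Tef (ENSMUSG00000022389, chromosome 15, 81802673 to 81826863, in GRCm38) rose from 14.9 ± 2.31 to 86.6 ± 11.8 CPM (counts scaled to the total of the mouse; SD, n = 5 each), with a log2 fold change of 2.53 (SE 0.17, adjusted p = 1.16e-05, edgeR quasi-likelihood test). Per3 (ENSMUSG00000028957, chromosome 4, 150997018 to 151044707) rose by 3.18 on the log2 scale (SE 0.29) and Per2 (ENSMUSG00000055866, chromosome 1, 91415977 to 91459351) by 3.24 (SE 0.36). Dbp (ENSMUSG00000059824, chromosome 7, 45705100 to 45710203) rose from 6.95 ± 3.20 to 89.0 ± 46.6 CPM, by 3.73 (SE 0.43, adjusted p = 0.000639). Npas2 (ENSMUSG00000026077, chromosome 1, 39193702 to 39363240) fell from 132 ± 38.9 to 15.2 ± 12.1 CPM, with a log2 fold change of -3.09 (SE 0.47, adjusted p = 0.00321). Arntl (ENSMUSG00000055116, chromosome 7, 113178471 to 113314126) had a log2 fold change of -2.12 (SE 0.52, adjusted p = 0.0214), and its call ended without ZT13 mouse 1 (adjusted p = 0.0674). Nr1d2 (ENSMUSG00000021775), Hlf (log2 fold change 2.28) and Rora (1.48) also rose, and Nfil3, a repressor at D-boxes, fell (-1.47), a call that ended with an offset for gene span (adjusted p = 0.0632). Nr1d1 was called (log2 fold change 1.23, adjusted p = 0.0416) but lost its call without ZT13 mouse 1, 2 or 5 or ZT1 mouse 1, 2, 3 or 5 (adjusted p = 0.0587 to 0.103).

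Among fibroblast genes outside the clock, Pik3ip1, an inhibitor of PI3-kinase, and the flavin monooxygenase gene Fmo2 rose by 1.75 (SE 0.17) and 1.78 (SE 0.21) on the log2 scale, and Fmo2 reached 1887 ± 480 CPM from 551 ± 135. Sntb1 rose by 1.71. Lpl, which encodes lipoprotein lipase, fell (386 ± 119 to 72.8 ± 31.2 CPM, log2 fold change -2.39, SE 0.29), and so did Angptl4, which encodes an inhibitor of that enzyme (-2.40, SE 0.33). The calcium-binding genes S100a6 (-1.04) and S100a16 (-1.31), the GTPase gene Rhoc (-0.90), Leo1 (-1.77), Mrpl52 (-1.05), Bloc1s1 (-0.99) and Dynll1 (-0.84) fell too. Eif1 fell by 0.81 on the log2 scale, and that call ended with an offset for gene span (adjusted p = 0.103). The cytokine gene Il6 fell from 203 ± 148 to 37.6 ± 16.0 CPM (log2 fold change -2.39, SE 0.51, adjusted p = 0.0121), and the vasodilator peptide gene Adm had a log2 fold change of -1.71 (SE 0.26). The chemokine gene Ccl2 (-2.57, SE 0.53), Junb (-0.97) and Nfkbia (-0.67) fell, and Tsc22d3, a target of the glucocorticoid receptor, rose (1.15). These 4 calls ended with the span offset, with adjusted p = 0.0611, 0.253, 0.411 and 0.0516 in that order.

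Of 8393 genes tested in fibroblasts, 1018 were called, 427 higher and 591 lower at ZT13, from 219 and 269 cells and 334971 to 1528046 UMIs per mouse. Among 17 tested genes of the core clock list, 9 rose and 3 fell, or 12 and 4 when adjusted over the list alone (camera adjusted p = 4.19e-11, and adjusted p = 0.00612 with an estimated correlation). Of 9 clock genes driven by E-boxes and D-boxes, 7 rose (9 adjusted over the list alone; adjusted p = 6.25e-24, and 0.00612 with an estimated correlation). Of the 4 tested genes of the positive arm and its phase, 3 fell (4 adjusted over the list alone; adjusted p = 6.22e-05, and 0.0433 with an estimated correlation). The list of inflammatory cytokines and NF-kB targets had 4 of 9 tested members lower (5 adjusted over the list alone; adjusted p = 0.000993, and adjusted p = 0.208 with an estimated correlation). Tnfaip2 lost its call without ZT13 mouse 1 or 2 (0.0642 and 0.0588), and Sod2 without any ZT13 mouse or ZT1 mouse 2, 3 or 4 (0.0672 to 0.118). The immediate early and dissociation list had 3 of 15 lower (3 adjusted over the list alone; adjusted p = 0.00441, and adjusted p = 0.45 with an estimated correlation; 0.677 with the span offset). Zfp36 lost its call without ZT13 mouse 2 (0.0501), and Ier2 without ZT13 mouse 1, 2 or 3 or ZT1 mouse 2 (0.056 to 0.0681). Chemokines had 2 of 10 lower (4 adjusted over the list alone; adjusted p = 0.0324, and adjusted p = 0.4 with an estimated correlation; 0.139 with the span offset), a call that ended without ZT13 mouse 5 (0.0552) or ZT1 mouse 3 (0.0814). Ccl7 lost its call in 8 of 10 omissions (0.0515 to 0.125). The hypoxia and glycolysis list had 2 of 11 lower (2 adjusted over the list alone; adjusted p = 0.0268, and adjusted p = 0.208 with an estimated correlation). Hk2 lost its call without ZT13 mouse 5 or ZT1 mouse 2, 3 or 4 (0.0569 to 0.0857). Cholesterol synthesis and uptake had 3 of 7 lower (5 adjusted over the list alone; adjusted p = 0.0268, and adjusted p = 0.45 with an estimated correlation), and its call ended without ZT1 mouse 3 (0.0882). Of its members, Fdps lost its call in 7 omissions and Insig1 in 6 (0.0508 to 0.115). The list of extracellular traps and oxidative burst had 2 of 3 lower (2 adjusted over the list alone; adjusted p = 0.0386, and adjusted p = 0.299 with an estimated correlation; 0.0738 with the span offset). These were Cyba, a subunit of NADPH oxidase, and the pore-forming gene Gsdmd, and the list's call ended without ZT13 mouse 4 (0.107) or ZT1 mouse 1 (0.0594). Cyba lost its call in 8 of 10 omissions (0.0788 to 0.123) and Gsdmd without ZT13 mouse 1 or 2 or ZT1 mouse 4 (0.0501 to 0.0601).

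The remaining fibroblast lists were not called. The glucocorticoid response list had 2 of 11 members higher (2 adjusted over the list alone, adjusted p = 0.0585), and it passed with the span offset. Extracellular matrix had 0 of 16 called (adjusted p = 0.109) and passed with that offset. Smooth muscle contractile genes had 0 of 8 called (0.191), leukocyte adhesion on endothelium 0 of 5 (0.86) and proliferation 0 of 3 (0.752). The heat shock and temperature list had 1 of 10 lower (0.261), and the foam cell and lipid handling list, which holds Lpl, 1 of 12 (1 adjusted over the list alone; 0.191). The count of called genes moved by over 1.5 times without ZT13 mouse 1 (484) or 2 (535), or without ZT1 mouse 2 (485) or 4 (577), and with the span offset (192 called, 156 of them shared). With that offset 26 of the 44 called genes that the naming rule gave still passed.

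Endothelial cells of the artery shared some of these clock differences. Rora, an activator of Arntl transcription, rose from 187 ± 23.9 to 464 ± 97.9 CPM (n = 5 each; log2 fold change 1.32, SE 0.17, adjusted p = 0.0042). Atp2b2, which encodes a plasma membrane calcium pump, rose by 1.94 on the log2 scale (SE 0.26), the adaptor gene Gab1 by 1.12 (SE 0.18) and Aph1b, a subunit of gamma-secretase, by 1.33 (SE 0.23). The mitochondrial gene Chchd2 fell from 826 ± 63.8 to 421 ± 30.5 CPM (log2 fold change -0.97, SE 0.12, adjusted p = 0.0026), and the tubulin gene Tuba1a had a log2 fold change of -1.23 (SE 0.17). Synpo2 rose (1.93, SE 0.34) and Hypk fell (-1.25, SE 0.19), calls that ended with the span offset (adjusted p = 0.0636 and 0.118). A further 6 genes rose, Cux1, Vps13a, Mapre2, Dusp16, Negr1 and Tef, and 7 fell, Rnaset2b, Tmsb10, Tubb3, Tubb4b, Tmem14c, Ndufa1 and Ndufb1-ps. Their calls ended without ZT13 mouse 5 (adjusted p = 0.0547 to 0.0586), and those of Dusp16 and Negr1 also without ZT1 mouse 3 (0.0511).

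Of the endothelial clock genes, Arntl fell from 50.7 ± 18.2 to 13.9 ± 8.12 CPM (log2 fold change -1.77, SE 0.36, adjusted p = 0.0219). Per3 (1.75, SE 0.40), Nr1d2 (1.03, SE 0.21) and Tef (1.31, SE 0.27) rose, whereas Dbp was not called (1.21, SE 0.43, adjusted p = 0.116). The Arntl call ended without ZT13 mouse 1 or 5 or ZT1 mouse 3 or 4 (adjusted p = 0.0511 to 0.0676), as did that of Tef (0.0544 to 0.0681). The Per3 call ended without ZT13 mouse 4 or ZT1 mouse 2, 3 or 4 (0.06 to 0.0769), and that of Nr1d2 without ZT13 mouse 5 or ZT1 mouse 3 or 4 (0.0553 to 0.0649). With the span offset Per3, Nr1d2 and Tef lost their calls (0.112, 0.0782 and 0.0615). The core clock list had 4 of 11 tested members higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00017, and 0.0443 with an estimated correlation). The E-box and D-box list had 3 of 6 higher (5 adjusted over the list alone; adjusted p = 2.89e-05, and 0.0312 with an estimated correlation). Leukocyte adhesion on endothelium, which covers Icam and Vcam genes, had 0 of 9 members called (adjusted p = 0.918). The foam cell and lipid handling list had 2 of 11 lower, Cd9 and Spp1 (2 adjusted over the list alone, adjusted p = 0.577). The Cd9 call ended without ZT13 mouse 1, 4 or 5 or ZT1 mouse 3 (0.0511 to 0.0687), and that of Spp1 without ZT13 mouse 1, 3, 4 or 5 or ZT1 mouse 3 (0.0527 to 0.0946).

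Of 6897 genes tested in endothelial cells, 276 were called, 80 higher and 196 lower at ZT13, from 122 and 268 cells and 188348 to 1592436 UMIs per mouse. All 122 cells at ZT1 came from the enriched library, against 44 at ZT13, where 224 came from the library of artery and blood. In the enriched libraries alone 0 of 5422 genes were called. Mitochondrial molecules made up 2.526% to 3.185% per mouse at ZT1 and 1.951% to 2.6% at ZT13, and with this share as a covariate 75 genes were called. DESeq2 called 519, and edgeR with no low-count filter 178. The count fell to 50, 97, 151, 95 and 11 without ZT13 mouse 1, 2, 3, 4 and 5, and to 180, 55 and 78 without ZT1 mouse 2, 3 and 4. With the span offset 22 were called, and 10 of the 25 called genes that the naming rule gave still passed.

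Macrophages of the artery had many called genes with small folds. Negr1, a cell adhesion gene, rose from 16.0 ± 4.74 to 108 ± 45.3 CPM (n = 5 each; log2 fold change 2.73, SE 0.32, adjusted p = 0.001). The long noncoding RNA gene Dleu2 rose by 0.63 on the log2 scale (SE 0.09), and the chromatin genes Baz1b and Lin54 by 0.66 (SE 0.10) and 0.74 (SE 0.12). Among genes of mitochondria, Chchd2 fell (590 ± 13.6 to 359 ± 12.8 CPM, log2 fold change -0.71, SE 0.07, adjusted p = 0.000638), as did Tspo, an outer membrane protein (-0.81, SE 0.09), and Cox6c (-0.67), Ndufa7 (-0.84) and Atp5md (-0.69). Of 78 respiratory chain genes 58 were called lower (median -0.52), and 8 of 76 with the span offset (median -0.27). Cyba fell by 0.71 on the log2 scale (1404 ± 101 to 859 ± 70.5 CPM), and Hypk (-1.23), Rnaset2a (-0.95), Ost4 (-0.82) and Gng5 (-0.73) fell too. Map3k5, Rasal2, Peli2, Rsrc1, Vps13b and Ankrd11 rose by 0.44 to 0.81 on the log2 scale, and the span offset ended these 6 calls (adjusted p = 0.094 to 0.317).

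Trem2, a lipid receptor of foam cells, had a log2 fold change of -0.62 (584 ± 61.5 to 377 ± 56.5 CPM, adjusted p = 0.00713), and the tetraspanin gene Cd9 of -0.89 (adjusted p = 0.00885). The chemokine receptor gene Cxcr4 (-0.89), Tnfaip2 (-0.75), the chemokine gene Ccl12 (-0.70) and the chaperonin gene Hspe1 (-0.45) fell. Of 10 tested macrophage markers 4 fell (median -0.28), and classical monocyte markers had a median of 0.86 with 0 of 5 called, so a change in the makeup of the macrophages is not excluded. With the span offset Trem2, Cxcr4, Tnfaip2, Ccl12 and Hspe1 lost their calls (adjusted p = 0.0647 to 0.437). Of the clock genes, Dbp rose from 5.83 ± 3.36 to 16.9 ± 8.52 CPM (log2 fold change 1.73, SE 0.40, adjusted p = 0.0183) and Tef by 1.31 (SE 0.27, adjusted p = 0.0112). The Dbp call ended without ZT13 mouse 2 (0.0537) or ZT1 mouse 3 (0.0526) or 4 (0.0665). RNA free in droplets held Dbp at 11.004 and 4.991 CPM in the ZT1 artery libraries and 68.656 and 32.022 CPM in those of ZT13. Arntl was not called (-0.28, SE 0.31, adjusted p = 0.629), nor were Per1, Per2, Nr1d1 and Nr1d2 (adjusted p = 0.095 to 0.461).

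Of 9057 genes tested in macrophages, 830 were called, 242 higher and 588 lower at ZT13, from 454 and 335 cells and 458193 to 3321751 UMIs per mouse. The core clock list had 2 of 13 tested members higher (4 adjusted over the list alone; camera adjusted p = 0.00717, and adjusted p = 0.292 with an estimated correlation), and the E-box and D-box list 2 of 6 (3 adjusted over the list alone; adjusted p = 0.00308, and adjusted p = 0.309 with an estimated correlation). In the artery and blood libraries alone neither clock list passed (adjusted p = 0.284 and 0.538). The extracellular matrix list had 2 of 9 lower (2 adjusted over the list alone; adjusted p = 0.00311, and adjusted p = 0.309 with an estimated correlation). These were Col3a1 and Lum, which fibroblasts make, at 13.7 and 21.3 CPM at ZT1. The Lum call ended with the span offset (0.0829), and the list did not pass in the enriched libraries alone (0.638). Antigen presentation by MHC class II had 1 of 7 higher, Ciita (1 adjusted over the list alone; adjusted p = 0.0737), which lost its call in 8 of 10 omissions (0.0631 to 0.0998). The list passed with the span offset and in the artery and blood libraries alone. The foam cell and lipid handling list had 3 of 16 lower (6 adjusted over the list alone; adjusted p = 0.141; Ctsd lost its call in 9 of 10 omissions, 0.0593 to 0.0919), and proliferation had 0 of 14 called (0.483). In the enriched libraries alone 1176 genes were called and in the artery and blood libraries alone 4, and without ZT13 mouse 3 or ZT1 mouse 2, 3 or 4 the counts were 530, 439, 549 and 449. With the span offset 83 genes were called, and 19 of the 39 called genes that the naming rule gave still passed.

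Fibroblasts differed from endothelial cells and from macrophages in some clock genes. Adjusted over the clock list alone, the log2 fold change of Dbp was higher in fibroblasts than in endothelial cells by 2.42 (SE 0.39, adjusted p = 0.0008), that of Nr1d1, which was not tested in endothelial cells by themselves, by 2.08, Nr1d2 by 1.15 and Tef by 1.14 (adjusted p = 0.00499 to 0.0133; edgeR, mouse as a block). Relative to fibroblasts, macrophages differed in 10 clock genes by the same adjustment. Per2 (-2.39), Dbp (-1.92), Per3 (-1.76), Nr1d2 (-1.75), Bhlhe41 (-1.54), Tef (-1.22) and Rora (-1.08) had lower log2 fold changes in macrophages, and Npas2 (4.06), Arntl (1.75) and Nfil3 (1.53) higher (adjusted p = 0.00218 to 0.0251). Npas2 and Per3 had too few counts to be tested in macrophages by themselves, so their values are uncertain. Between endothelial cells and macrophages 0 clock genes differed (smallest adjusted p = 0.0561, Npas2). Adjusted over all genes, 1 of 9259 genes differed between endothelial cells and fibroblasts, and 0 of 9777 and 0 of 10465 in the pairs with macrophages, and no clock gene was called there.

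**Figure D1:**
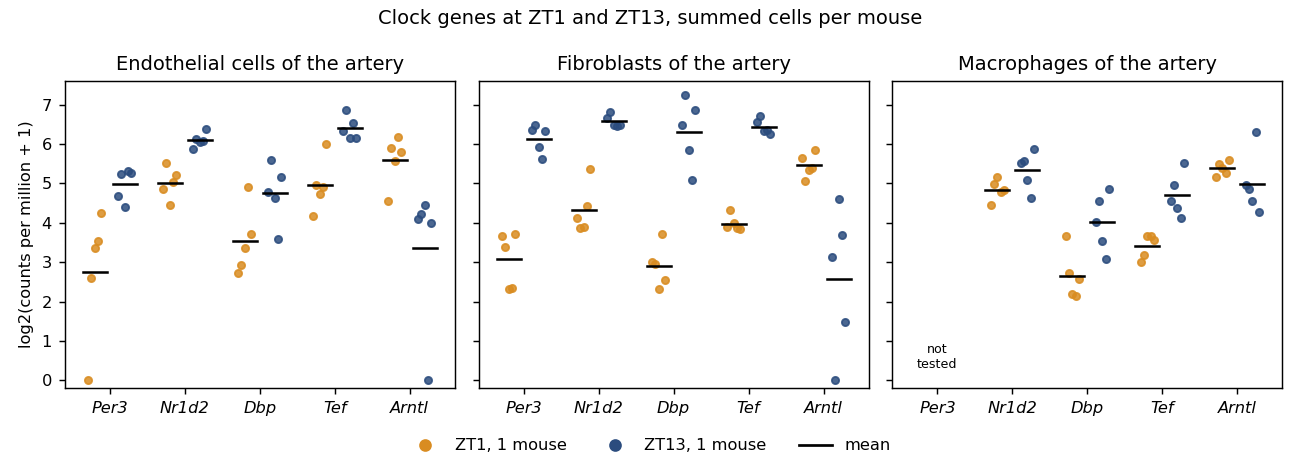
Log2 of CPM plus 1 (y axis) for 5 clock genes (x axis) in endothelial cells, fibroblasts and macrophages of the artery, with a point for each mouse (5 at ZT1, 5 at ZT13) and a bar at the mean. In fibroblasts the ZT13 points of Tef, around a mean of 86.6 CPM, lie above all ZT1 points, around 14.9 CPM, and Per3 was not tested in macrophages.

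Cluster 12 of the artery lost macrophage genes at ZT13. The complement genes C1qb (529 ± 166 to 29.4 ± 24.7 CPM, log2 fold change -4.17, SE 0.44, adjusted p = 0.00262), C1qa (-3.35) and C1qc (-4.31) fell, as did Ms4a7 (-3.29, SE 0.28, adjusted p = 0.000697), the transcription factor gene Maf (-2.55), Aif1 (-1.79), the Fc receptor gene Fcgr1 (-1.96), Ifi211 (-1.55) and Trem2 (-3.28). Of 8 tested macrophage markers 6 fell (median log2 fold change -2.66), so the cells under this number need not be alike at the 2 times. The chemokine gene Ccl6 (1020 ± 634 to 154 ± 33.3 CPM, -2.73) fell. Klrb1b, a lectin receptor gene, rose by 2.56 (SE 0.30), the transcription factor gene Stat4 by 2.86 (SE 0.37), the costimulator gene Cd80 by 1.42 (SE 0.19) and Map3k14, a kinase of the noncanonical NF-kB pathway, by 1.85 (SE 0.23). Rhoq, Fnbp1, Ramp3, Stk38l and Ttc28 rose by 1.498 to 3.76 on the log2 scale. The interferon list had 1 of 8 higher, Rsad2 (1.85), and 1 lower, Ifi27l2a (-1.15; camera adjusted p = 0.264). The immediate early list had 2 of 15 higher, Fosb (2.01) and Btg2 (1.20), and 2 lower, Ier3 (-2.41) and Klf6 (-0.84; camera adjusted p = 0.951). The Rsad2 call ended without ZT13 mouse 5 (0.107) or ZT1 mouse 4 (0.0509), and that of Klf6 without ZT13 mouse 4 or 5 or ZT1 mouse 3, 4 or 5 (0.0539 to 0.081). Cxcl3 stood at 89.9 ± 44.9 CPM at ZT1 (n = 4) and at 0 in all 3 ZT13 mice, and its call ended without ZT13 mouse 5 (adjusted p = 0.0515).

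Of 5850 genes tested in cluster 12, 378 were called, 204 higher and 174 lower, in 4 mice at ZT1 and 3 at ZT13 with 148 and 47 cells and 252000 to 840384 UMIs per mouse. Chemokines had 7 of 13 members lower (9 adjusted over the list alone; camera adjusted p = 5.44e-07, and adjusted p = 0.192 with an estimated correlation). Without ZT13 mouse 5 only Ccl6 of the 7 kept its call, and Cxcl3, Cxcl2, Ccl2, Ccl7, Ccl12 and Ccl9 lost theirs (0.0515 to 0.139). Ccl2 and Ccl7 also lost them without ZT13 mouse 1, Cxcl2 and Ccl12 without ZT13 mouse 4, Cxcl2, Ccl2, Ccl7 and Ccl9 without ZT1 mouse 4, Ccl2 and Ccl7 without ZT1 mouse 5, and Ccl7 without ZT1 mouse 3 (0.0518 to 0.098). The foam cell and lipid handling list had 3 of 15 lower (8 adjusted over the list alone; adjusted p = 0.000573, and adjusted p = 0.59 with an estimated correlation), and it did not pass in the artery and blood libraries alone (0.195). Of its 3, Trem2 kept its call in each omission. Plin2 and Spp1 lost theirs without ZT13 mouse 4 or 5 or ZT1 mouse 4 (0.0518 to 0.155), and Plin2 also without ZT1 mouse 3 or 5 (0.0689 and 0.104). Antigen presentation by MHC class II had 1 of 8 higher, H2-Oa (5 adjusted over the list alone; adjusted p = 0.00125, and adjusted p = 0.559 with an estimated correlation). Dendritic cell markers moved the same way (1 of 5 tested rose, median 1.80), so a change in the makeup of the cluster is not excluded. The H2-Oa call ended without ZT13 mouse 5 (0.0719) or ZT1 mouse 4 (0.0502). The trap and oxidative burst list had 3 of 8 lower (4 adjusted over the list alone; adjusted p = 0.0456, and adjusted p = 0.559 with an estimated correlation). Of its members, Cyba and Cybb lost their calls in 6 of 7 omissions (0.0625 to 0.154). The call of the list ended without ZT13 mouse 5 (0.114) or ZT1 mouse 3 (0.0895), with the span offset (0.0641) and in the artery and blood libraries alone (0.268). The counts were 639, 213 and 90 without ZT13 mouse 1, 4 and 5, and 203, 152, 92 and 152 without ZT1 mouse 2, 3, 4 and 5. With the span offset 133 genes were called, and 231 and 108 in the enriched and in the artery and blood libraries alone, with 5 cells per mouse. With that offset 30 of the 45 called genes that the naming rule gave still passed, and Plin2, Cxcl2, Cyba, Ccl2, Ccl7, Ccl12, Ccl9 and Klf6 did not (adjusted p = 0.0545 to 0.14).

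Gene span and library moved with these differences. Across genes, which are not independent replicates, the log2 fold change rose with the genomic span of the gene in fibroblasts (Spearman 0.565), endothelial cells (0.545), macrophages (0.524) and cluster 12 (0.464), and little in blood neutrophils (0.0273). Ribosomal protein and respiratory chain genes, which are short, had medians of -0.60 in fibroblasts, -0.44 in endothelial cells and -0.40 in macrophages. Within macrophages of the same mice, these genes differed by -0.17 between the 2 libraries of ZT1 and by 0.20 between those of ZT13. Between the times they differed by -0.58 in macrophages of the enriched libraries and by -0.17 in those of artery and blood. Haemoglobin RNA, which enters droplets from red cells, was lower at ZT13 in the 3 types: Hbb-bs fell from 308 to 13.9 CPM in endothelial cells, and by 3.08 and 2.47 on the log2 scale in fibroblasts and macrophages. In free RNA of the enriched libraries Hbb-bs stood at 14068 CPM at ZT1 and 9924 CPM at ZT13. In that of the artery and blood libraries it stood at 221 CPM at ZT1 and 1694 CPM at ZT13. All ZT1 endothelial cells came from the enriched library and most ZT13 ones from the library of artery and blood. The endothelial fall in Hbb-bs cannot be told from this mix. The mix moved the same way in macrophages, with 335 and 119 cells from the enriched libraries of ZT1 and ZT13 against 119 and 216 from the others. It moved less in fibroblasts (212 and 196 against 7 and 73), so the falls in these types need not be free of it.

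Cell types of artery cells that were not enriched differed between times in 7 of 15 types tested, in 4 mice at ZT1 and 5 at ZT13. No endothelial cell was seen at ZT1, and at ZT13 these cells made up 32.3% ± 8.97 (SD, 224 cells). Fibroblasts made up 1.974% ± 1.398 at ZT1 and 10.05% ± 3.599 at ZT13. Cluster 12 was lower at ZT13 (17.04% ± 5.78 to 5.10% ± 2.73), as were B cells (6.41% ± 3.15 to 1.14% ± 0.712) and T cells (6.38% ± 2.66 to 1.57% ± 1.64). Cluster 27, led by the gamma-delta T cell gene Trdc and by Il23r, fell from 7.13% ± 1.75 to 1.52% ± 1.30, and cluster 31, led by the lymphoid precursor genes Rag1 and Dntt, from 5.52% ± 2.41 to 0.207% ± 0.287. Each of the 7 had p = 0.0079 in an exact two-sided permutation test, the smallest value that 126 regroupings allow (adjusted p = 0.017 over 15 types). Macrophages (32.9% ± 12.8 and 28.9% ± 9.23, exact p = 0.595) and neutrophils (2.88% ± 2.33 and 2.09% ± 0.98, exact p = 0.524) did not pass, nor did dendritic cells (4.68% and 5.83%) and non-classical monocytes (5.55% and 2.32%, adjusted p = 0.0744 in the exact test). Without any single ZT13 mouse the number of types that passed was 0 (adjusted p = 0.05 to 0.0612), because with 4 against 4 mice the smallest p of the exact test, which the 7 types reached, did not adjust below 0.05. The differences stayed near their size there, at 28.7 to 34.5 points for endothelial cells and -12.5 to -10.8 for cluster 12, and without ZT1 mouse 3 the T cell share ended (0.0714). Over leukocytes alone 0 of 13 types passed. There the B cell share in non-enriched artery (-4.68 points) and the Cluster 31 share in non-enriched artery (-5.30 points) were at the smallest p of the exact test, which did not adjust below 0.05 (adjusted p = 0.0516), while cluster 12, cluster 27 and T cells were not.

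**Figure D2:**
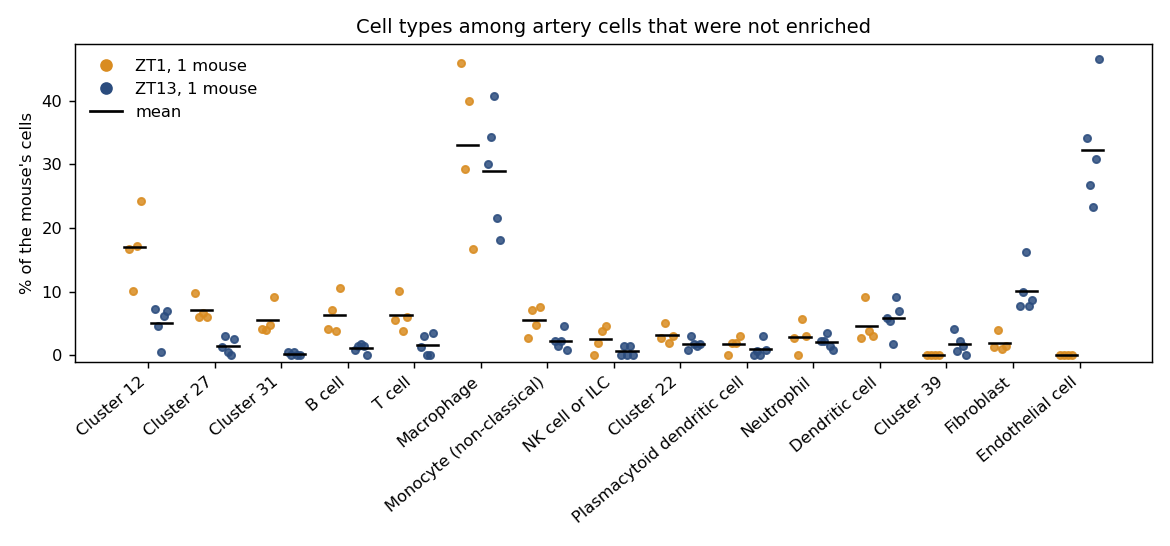
Percent of each mouse's cells (y axis) for 15 cell types (x axis) in artery cells that were not enriched, with a point for each mouse (4 at ZT1, 5 at ZT13) and a bar at the mean. Endothelial cells are at 0 in every ZT1 mouse and average 32.3% at ZT13, while cluster 12 averages 17.04% at ZT1 and 5.10% at ZT13.

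In blood of the same mice monocytes were a smaller share of the captured cells at ZT13, and B and T cells a larger one. Shares sum to 100%, so a rise of a type lowers others. Classical monocytes made up 17.97% ± 7.73 of blood cells at ZT1 and 3.11% ± 3.02 at ZT13 (n = 5 each, exact permutation p = 0.0159, adjusted p = 0.0317 over 6 types), and non-classical monocytes 12.3% ± 7.46 and 1.84% ± 1.54 (exact p = 0.0079, adjusted p = 0.0238). B cells made up 2.28% ± 1.65 and 12.96% ± 4.92 (exact p = 0.0079, adjusted p = 0.0238), and T cells 0.809% ± 1.23 and 7.23% ± 4.62 (exact p = 0.0238, adjusted p = 0.0357). The T cell difference lost its call without ZT1 mouse 1, 2 or 5 (adjusted p = 0.0833) or 4 (0.0714). Neutrophils were the main type at both times (61.1% ± 9.86 and 65.7% ± 8.24, exact p = 0.444), and NK cells did not pass (2.20% and 5.26%, adjusted p = 0.114 in the exact test). The 10 blood samples rest on 6 types with 2 to 277 cells per time. The metadata list these cells as not sorted, whereas the plan for these shares placed blood within the Gr1-positive lineage-negative and Kit-positive gates. Which holds is not known here, so these shares need not be those of whole blood.

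Neutrophils of blood by mouse differed between times in few single genes. Gphn, which encodes gephyrin, fell from 451 ± 71.4 to 162 ± 11.8 CPM (n = 5 each; log2 fold change -1.46, SE 0.17, adjusted p = 3.17e-05), and Cmss1 and the mitochondrial tRNA synthetase gene Lars2 had log2 fold changes of -0.75 (SE 0.12) and -0.99 (SE 0.17). The other called gene, Gm42418 (log2 fold change -1.36), falls outside the naming rule and was named after its values were seen. Its locus overlaps a ribosomal RNA repeat, so its value is uncertain. Gphn, Gm42418 and Lars2 also passed the size rule as higher at ZT1 in 5, 5 and 4 of the pooled organs. Outside the Kit-enriched cells they passed in 1, 1 and 2 organs. Whether the called genes share a common source, such as that repeat, was not tested, so the values of the other 3 are uncertain too. The protease inhibitor gene Cstdc4 (1.17, SE 0.28, adjusted p = 0.082) and the granule gene Lcn2, a binder of bacterial siderophores (0.76, SE 0.22, adjusted p = 0.224), had the lead among genes higher at ZT13 but were not called, like Rflnb, Atg2a and Hist2h2aa1 (adjusted p = 0.196 to 0.243). Lrmda (-0.72) and AU019990 (-0.90) were not called either (both adjusted p = 0.0778), nor was Per1, the only clock gene tested by rule (-0.25, adjusted p = 0.944). Of 2505 genes tested by edgeR, 4 were called, all lower, from 123 and 277 cells and 80699 to 344330 UMIs per mouse, against 196 at an unadjusted p under 0.05 and 17 by DESeq2. The count was 7 without ZT13 mouse 4 and 15 without ZT1 mouse 1. Mitochondrial molecules made up 0.217% to 0.453% per mouse at ZT1 and 0.195% to 0.277% at ZT13.

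Interferon response genes were lower as a group in these neutrophils. None of the 9 tested members was called over all genes and 4 were lower when adjusted over the list alone (median log2 fold change -0.69, camera adjusted p = 2.19e-05, and adjusted p = 0.371 with an estimated correlation). Ifit1 (175 and 77.5 CPM, log2 fold change -1.18), the antiviral gene Rsad2 (-0.93) and the ubiquitin-like gene Isg15 (-0.74) were among the lowest values. The list of secondary and tertiary granules had 0 of 6 called (2 higher adjusted over the list alone; adjusted p = 0.00859, and adjusted p = 0.371 with an estimated correlation), and its call ended without ZT13 mouse 1 (0.117). Ageing and homing genes, which include Cxcr4 and Cxcr2, had 0 of 10 called (1 lower adjusted over the list alone; adjusted p = 0.356). The inflammatory and NF-kB list (0 of 9, adjusted p = 0.695) and the trap and oxidative burst list (0 of 7, adjusted p = 0.881) were not called.

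Neutrophils of the artery were set against blood neutrophils of the same mice, in 7 mice with 3 or more arterial neutrophils, 5 of them at ZT13. Nfkbia, an inhibitor of NF-kB that NF-kB itself induces, rose from 216 ± 67.9 CPM in blood to 2998 ± 815 in the artery (n = 7; log2 fold change 3.80, SE 0.22, adjusted p = 1.38e-10, higher in 7 of 7 mice). The chemokine gene Cxcl2 (4.49, SE 0.55), the ubiquitin editor gene Tnfaip3 (3.77, SE 0.43), the lipopolysaccharide receptor gene Cd14 (3.6039, SE 0.34), the inflammasome gene Nlrp3 (2.13, SE 0.28) and Il1b (0.95, SE 0.16) rose. Slc7a11, a cystine transporter gene, rose by 3.33 to 5316 ± 1905 CPM, and Mpp7 (4.98), Ier3 (3.31), Pik3ap1 (3.01), Irak2 (2.86), Acod1, which makes itaconate (2.83), Morrbid (2.76) and the kinase gene Pim1 (2.06) rose too. Cxcr4, a receptor of bone marrow homing, rose by 1.34 (SE 0.32, adjusted p = 0.00427) and the lipid droplet gene Plin2 by 2.31 (SE 0.37). Sfxn5 (1043 ± 195 to 260 ± 138 CPM, log2 fold change -2.02), Mtus1 (-2.97), Tbc1d14 (-1.96), Adam19 (-2.62), Svil (-1.41), Map3k5 (-1.42), Prr5l (-1.91), Hacd4 (-2.52), March1 (-2.58) and the glycogen phosphorylase gene Pygl (-1.29) fell. The granule collagenase gene Mmp8 fell by 1.06 on the log2 scale and Ifi27l2a by 1.14. Padi4, which citrullinates histones, was also lower (-1.19, adjusted p = 0.0213), and its call ended without ZT13 mouse 3 or ZT1 mouse 2 or 4 (0.0653 to 0.0751).

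Of 1535 genes tested between artery and blood, 407 were called, 213 higher and 194 lower in the artery, from 14354 to 344330 UMIs per mouse and tissue. All 10 tested members of the inflammatory and NF-kB list rose (10 adjusted over the list alone; camera adjusted p = 2.68e-15, and 0.00716 with an estimated correlation). The Ptgs2 call ended without ZT13 mouse 1 (0.071) or ZT1 mouse 4 (0.102). Markers of non-classical monocytes were also higher in the artery (2 of 2 tested, median 2.21) and 3 of 8 neutrophil markers lower (median -0.49), from 3 to 13 arterial cells per mouse, so a share of other cells is not excluded. Foam cell and lipid handling had 4 of 9 higher (5 adjusted over the list alone; adjusted p = 0.0375, and adjusted p = 0.294 with an estimated correlation), and the immediate early and dissociation list 4 of 10 (4 adjusted over the list alone; adjusted p = 0.0375, and adjusted p = 0.294 with an estimated correlation). Of the latter, Btg2 lost its call without ZT13 mouse 1, 3, 4 or 5 or ZT1 mouse 4 (0.0684 to 0.0846). Interferon response had 3 of 5 lower (3 adjusted over the list alone; adjusted p = 0.0865), ageing and homing 4 of 10 higher (4 higher and 1 lower adjusted over the list alone; 0.212), secondary and tertiary granules 1 of 5 lower (1 adjusted over the list alone; 0.239) and glucocorticoid response 0 of 4 called (0.86). Of the lower interferon genes, Rsad2 lost its call without ZT1 mouse 2 (0.0539) or 4 (0.0506) and Oasl2 without ZT1 mouse 4 (0.052). The artery was digested with enzymes at 37 °C for 1 hour and blood was lysed on ice, so tissue and preparation cannot be told apart. The version with 3 or more cells from all artery libraries was chosen after seeing the data, because fewer than 3 mice had the planned 10 cells, and in the libraries that hold both tissues it called 181 genes.

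**Figure D3:**
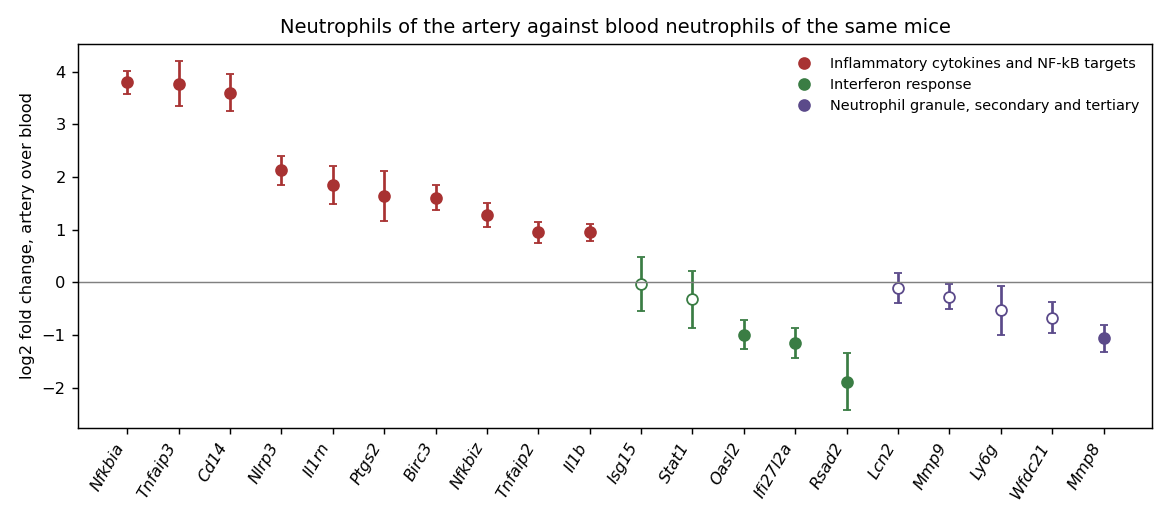
Log2 fold change of artery over blood neutrophils (y axis) for 20 genes of 3 lists (x axis), with the SE as bars, from 7 mice, and filled points for called genes. The 10 inflammatory and NF-kB genes lie between 0.95 and 3.80, and the called interferon genes between -1.88 and -0.99.

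Neutrophils of the pooled organs had 1 sample per organ and time, so no test over mice was run, and intervals are exact 95% Poisson intervals that cover counting error only. Genes past the size rule, higher at ZT13 and higher at ZT1, numbered 253 and 223 in bone marrow, 374 and 411 in blood, 240 and 165 in spleen, 257 and 284 in lung perfusate, and 490 and 183 in liver perfusate. TMM scaling shifted the liver ratios by -0.10 on the log2 scale and gave 272 and 349 there. Cells at ZT1 and ZT13 numbered 297 and 557 in bone marrow, 614 and 980 in blood, 152 and 195 in spleen, 293 and 684 in lung and 221 and 728 in liver, with 3510 to 7430 UMIs per cell. The antimicrobial peptide gene Camp was higher at ZT1 in spleen (4803 CPM, interval 4643 to 4967, against 429, interval 383 to 480) and liver (1110 against 213 CPM), and so was the granule gene Ltf in liver (727 against 175 CPM). These sums include the Kit-enriched cells, without which the granule list turned in both organs. In bone marrow Ifit2, an interferon target, was higher at ZT1 (32.6 against 3.603 CPM), and Hbb-bs was higher at ZT13 (379 against 4.985 CPM). Hba-a1 was at least 90.9-fold higher there, against a floor of 3 counts. Free Hbb-bs RNA stood at 522 CPM in the pooled ZT1 library and 2180 CPM in that of ZT13, so these haemoglobin counts need not come from neutrophils.

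Across organs, 110 genes passed the size rule in the same direction in 4 or more of the 5 organs, 66 higher at ZT13 and 44 higher at ZT1 (47 and 60 with TMM scaling). The protease inhibitor gene Wfdc17 was higher at ZT13 in all 5 organs (log2 ratio 0.97 to 1.96), as were Ifitm1, a restriction factor of viral entry (0.77 to 1.25), the metalloreductase gene Steap4 (0.59 to 1.34), the chemokine receptor gene Cxcr2 (0.29 to 0.45) and Lrg1 (0.36 to 0.65). Higher at ZT1 in all 5 were Ifi27l2a (-0.56 to -0.35), the lipid droplet gene Plin2 (-1.17 to -0.61), Gphn (-0.75 to -0.55), the tetraspanin gene Cd9 (-0.57 to -0.30) and Camp (-3.48 to -0.29). Outside the Kit-enriched cells, an alternative chosen after seeing the data, 9 of the 66 and 2 of the 44 passed in 4 or more organs. Wfdc17, Ifitm1 and Ifi27l2a passed in 5 of them, Cxcr2 and Lrg1 in 4, Plin2, Cd9 and Camp in 3, Steap4 in 2 and Gphn in 1.

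Gene lists in pooled neutrophils followed the same libraries. The interferon list summed to less at ZT13 in each organ, with 4731 CPM (interval 4646 to 4817) and 3287 CPM (3227 to 3348) in blood and 2095 and 1442 CPM in bone marrow. Members with separate intervals were lower in 11 of 14 measured in blood, 8 of 14 in bone marrow, 4 of 11 in spleen, 3 of 14 in lung and 1 of 14 in liver. Among 10000 random lists matched on expression, the list's median lay at percentile 0.00 in bone marrow and blood, 0.01 in spleen, 0.16 in lung and 13.5 in liver. Such percentiles compare genes within 1 sample per time and do not cover differences between mice. Ageing and homing genes summed higher at ZT13 in all 5 organs, by most in spleen (7513 and 8708 CPM), but in 1 of 5 outside the Kit-enriched cells. Secondary and tertiary granule genes were lower at ZT13 in spleen (23592 and 7895 CPM) and liver (9942 and 6811 CPM) and higher in blood (5369 and 6035 CPM), lung (4785 and 6299 CPM) and bone marrow (44282 and 45466 CPM). Outside the Kit-enriched cells the spleen and liver differences turned, with log2 ratios of 0.38 and 0.13. Primary granule genes had overlapping intervals at both times in each organ, with 24.02 and 29.65 CPM in bone marrow.

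**Figure D4:**
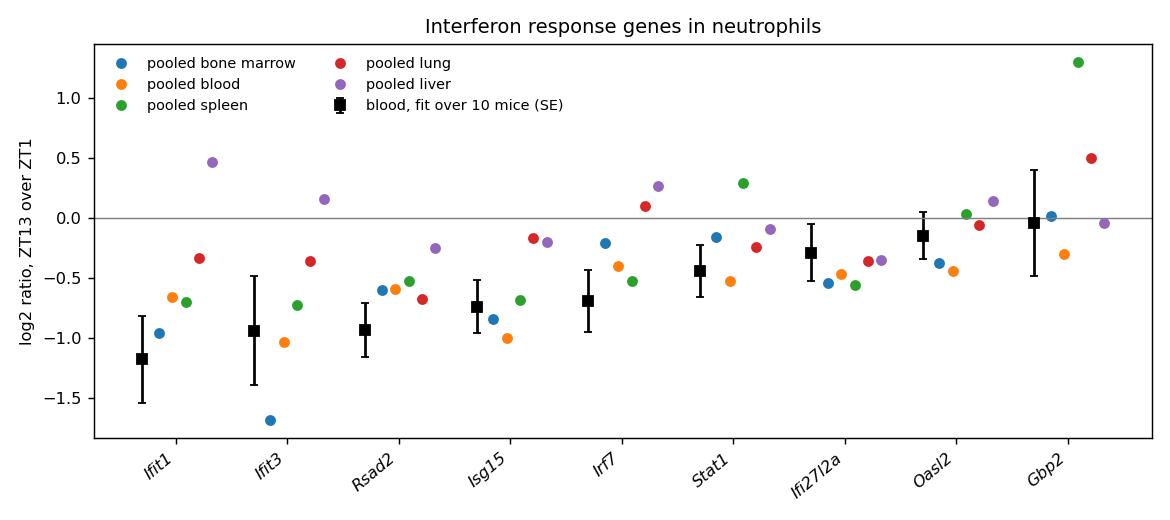
Log2 ratio of ZT13 over ZT1 (y axis) for 9 interferon response genes (x axis) in neutrophils, as squares with SE from the fit over 10 mice of blood by mouse and as points for 5 pooled organs, 1 sample each per time. Ifit1 lies at -1.18 in blood by mouse, and Gbp2 at -0.04 there.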

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

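The tests of explanations in this part were chosen after seeing the data.

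P1, the lower ribosomal protein and respiratory chain transcripts at ZT13, may come from library or gene span rather than time. The 2 artery libraries of the same mice differed by -0.172 at ZT1 and by 0.1969 at ZT13 in macrophages. Between the times these genes differed by -0.5789 in macrophages of the enriched libraries and by -0.1697 in those of artery and blood. The latter is no larger than the differences between libraries of 1 time. With the span offset the medians were -0.2627 in fibroblasts, -0.1298 in endothelial cells and -0.1148 in macrophages, so part of the shift stayed, most in fibroblasts. Neither explanation can be told from time for the whole pattern. Free RNA shifted the other way, by 0.2129 and 0.4404, which speaks against free RNA of broken cells as the source of the fall. Loss of cytoplasm would raise these genes in free RNA and nuclear RNA in the cells. The 2 free RNA shifts go with that. Malat1 was at -0.2803 in macrophages and Neat1 at 0.65 in fibroblasts, neither called, so loss of cytoplasm stays open.

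P2, the absence of endothelial cells from the ZT1 artery that was not enriched, is unlikely to come from the gene, mitochondrial or hashtag filters. Among the deposited barcodes of that library, 2 carried 4 or more endothelial markers against 276 at ZT13. These barcodes had already passed cell calling, so the count cannot speak to loss at that step. Broken cells would leave RNA, but free Vwf stood at 5.141% and Cdh5 at 1.449% of the ZT13 library. The enriched ZT1 library of the same mice held 122 endothelial cells, so their arteries did hold such cells. Fibroblasts were scarce in the ZT1 library that was not enriched too, with 12 barcodes with 4 or more of their markers against 120 at ZT13. Free Dcn stood at 59.5 against 544 CPM and free Acta2 at 22.9 against 125 CPM, so the loss was not limited to endothelial cells. A difference in dissection or digestion could give the same result and was not tested.

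P3, the lower interferon list in blood neutrophils, was also seen in pooled blood of the other pair of libraries (median log2 ratio -0.5809). Within the cluster with most blood neutrophils (209 cells, against 189 in the next), the median was -0.6853. There 9 of 9 members were lower (camera adjusted p = 4.97e-07, and 0.0643 with an estimated correlation). A mixture of clusters is thus unlikely to be the only source. The next cluster was not tested, and Rsad2 is among the leading genes of the tested one, so a mixture within it is not excluded.

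Regrouping mice over the times, or swapping tissue within mice for artery against blood, gave fewer called genes than the real grouping. The real grouping was 1 of 100 splits with as many calls in endothelial cells (highest other 2), fibroblasts (10), macrophages (8) and blood neutrophils (1), 1 of 35 in cluster 12 (1) and 1 of 64 between artery and blood (59).

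Single mice stood apart in 11 of 80 groups, where chance gives about 1 in 20 groups, or 4. In endothelial cells Arntl was 0 CPM in ZT13 mouse 4 (others 14.957 to 20.985) and Dbp 29.184 in ZT1 mouse 4 (5.642 to 12.114). In fibroblasts Nr1d2 was 39.988 in ZT1 mouse 5 (13.517 to 20.337). In macrophages Arntl was 77.603 in ZT13 mouse 4 (18.256 to 30.032), Nr1d1 5.54 in ZT13 mouse 3 (13.277 to 15.02) and Dbp 11.612 in ZT1 mouse 1 (3.413 to 5.657). In the artery the share of cluster 27 was 9.722% in ZT1 mouse 2, cluster 31 9.091% in ZT1 mouse 5, dendritic cells 9.091% in ZT1 mouse 3, fibroblasts 16.279% in ZT13 mouse 3 and plasmacytoid dendritic cells 3.077% in ZT13 mouse 4.

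Change with time differed between types for clock genes, adjusted over the clock list alone. From endothelial cells to fibroblasts it was higher by 2.0774 for Nr1d1, 1.1495 for Nr1d2, 2.4187 for Dbp and 1.1369 for Tef. From fibroblasts to macrophages it differed by 1.7498 for Arntl, 4.0647 for Npas2, -2.3941 for Per2, -1.7598 for Per3, -1.7494 for Nr1d2, -1.916 for Dbp, -1.2195 for Tef, -1.5393 for Bhlhe41, 1.5344 for Nfil3 and -1.078 for Rora.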

How the results depend on the processing

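The span offset, the mitochondrial covariate, the library subsets with 5 cells, the artery and blood version with 3 cells, leukocytes alone and cells outside the Kit-enriched hashtags were chosen after seeing the data.

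In fibroblasts the 1018 called genes became 192 with the span offset and 416 with the mouse number as a replicate block, and 484 to 1217 without 1 mouse. Mouse numbers do not pair animals, with correlations of -0.1121 to 0.2247. The 9 lists became 3 with an estimated correlation, and 7 to 12 without 1 mouse.

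In endothelial cells the 276 genes became 519 with DESeq2, 178 with no low-count filter, 0 in the enriched libraries with 5 cells, 17 with the replicate block, 22 with the span offset and 75 with the mitochondrial covariate, and 11 to 214 without 1 mouse. The immediate early list turned to higher at ZT13 with the span offset (adjusted p = 0.02268).

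In macrophages the 830 genes became 2611 with the top hashtag rule, 4 in the artery and blood libraries and 83 with the span offset, and 439 to 781 without 1 mouse. The 3 lists became 0 with an estimated correlation, 5 with fry and 8 with the span offset, and 3 to 5 without 1 mouse. The core clock list had adjusted p = 0.2917 with an estimated correlation, 0.1047 in the enriched and 0.2837 in the artery and blood libraries. The chemokine list turned to higher in the latter (0.003965).

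In cluster 12 the 378 genes became 894 with no low-count filter, 231 and 108 in the enriched and in the artery and blood libraries with 5 cells and 133 with the span offset, and 90 to 639 without 1 mouse. The 4 lists became 0 with an estimated correlation, 0 with fry and 2 in the artery and blood libraries.

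In blood neutrophils the 4 genes became 17 with DESeq2, 16 with no low-count filter and 8 with 20 cells, and 4 to 15 without 1 mouse. The 2 lists became 0 with an estimated correlation and 0 with fry, and 1 to 3 without 1 mouse. Between artery and blood the 407 genes became 770 with no low-count filter, 166 and 181 in the libraries with both tissues with 5 and 3 cells, and 535 with no replicate block, and 282 to 405 without 1 mouse.

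The 7 artery shares became 0 over leukocytes alone, where B cells and cluster 31 stayed at the smallest p, which did not adjust below 0.05. They became 6 to 9 without 1 ZT1 mouse and 0 without 1 ZT13 mouse, where with 4 against 4 mice the smallest p did not adjust below 0.05 and the differences stayed near their size. The 4 blood shares became 3 to 5 without 1 mouse. In pooled neutrophils the top hashtag rule gave 1066 genes in liver. Outside the Kit-enriched hashtags 254 genes passed in bone marrow, 218 in blood, 59 in spleen, 260 in lung and 251 in liver, and 16 in 4 or more organs. There the granule sum was higher at ZT13 in 5 organs, having turned in spleen (0.3761) and liver (0.1296), and the ageing and homing sum in 1.

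Of 4384 gene results over all alternatives, 3769 stayed, 585 lost and 19 gained a call, 11 moved and 0 turned. For lists these were 854, 39, 37, 63 and 2 of 995, for shares 229, 45, 4, 5 and 0 of 283, and for organ sums 33, 0, 0, 5 and 2 of 40.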

Other observations

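The observations in this part were chosen after seeing the data.

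Cluster 31 of the artery, led by Arpp21, Dntt and Rag1, had 20 cells at ZT1 and 2 at ZT13 among cells that were not enriched, 18 of the 20 in the 4 mice of the share test. The enriched library of ZT1 held 18 and that of ZT13 held 0. Free Rag1 RNA stood at 19.1 and 1.02 CPM in the artery and blood libraries of ZT1 and ZT13, and at 7.475 and 0.66 CPM in the enriched ones. Over leukocytes alone the Cluster 31 share in non-enriched artery was lower by 5.298 points at ZT13, at the smallest p of the exact test (adjusted p = 0.0516).

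In pooled neutrophils of bone marrow the MHC class II list had 2 of 4 measured members higher at ZT13 (median log2 ratio 0.95, percentile 99.98). The glucocorticoid list had 6 of 12 higher in liver (percentile 97.54). The heat shock list lay at percentile 99.01 in blood and 99.2 in spleen, and the NF-kB list at 99.54 in bone marrow and 0.14 in lung.

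Artery types with too few cells for a test were smooth muscle cells (82 at ZT1 and 58 at ZT13), modulated smooth muscle cells (38 and 18), dendritic cells (44 and 47) and mesothelial cells (17 and 4).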
